A study of Mus musculus with 6 samples.

How the data were processed

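RNA was measured by directional total RNA sequencing (NEBNext Ultra II Directional kit, per the labels) in 6 libraries from the brain of mice that carry Tie2-cre and NuTRAP. The titles of all 6 libraries carry the genotype label WT. NuTRAP is a reporter that Cre switches on. It labels ribosomes with EGFP and nuclei with mCherry in cells where Cre has switched it on. Brains were dissociated into cell suspensions, and cells that were EGFP positive, CD31 positive and CD11b negative were sorted as endothelial cells, per the labels' protocols. The 3 libraries called Input come from the suspension and the 3 called Positive from the sorted cells, with replicate numbers 1222, 1223 and 1227 in each fraction. The series text calls the 3 replicates biological.

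The deposited table holds 10989 genes with estimated counts (raw columns, mostly not whole numbers) and log2 normalised values for each library. Per the file headers, genes were kept where all libraries of at least 1 of the 2 conditions had a raw value of at least 50, and this held for all 10989 genes when tested. It leaves out genes that were low in both fractions, and of the genes kept 8509 passed in both fractions, 1897 in Input only and 583 in Positive only. Per the submitters' processing notes the genome build was mm10 and the tool names include DESeq; the aligner, the gene counter and the use of strand in counting are not given in the sources used here. The deposited log2 values equal the log2 of the estimated counts with 1 scaling factor per library and minus 1 constant per gene, whose definition the file does not state; they were used only as an alternative. Coordinates are those of the deposited table, 1-based on mm10. No gene of the mitochondrial chromosome was analysed here, so the list of mitochondrially encoded genes fixed in advance has no result, and mitochondrial read shares were not analysed here.

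The deposited estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood test of Positive against Input with fraction as the only term. The filter removed 0 genes, since the deposited table had already been filtered, so the setting without a filter could not move anything. Benjamini-Hochberg adjusted p below 0.05 was the threshold. Levels are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries, and log2 fold changes are edgeR's fitted values (prior count 2) with their standard errors (SE). The TMM factors ran from 0.94 to 1.082, and the biological coefficient of variation was 21.6%.

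Before the data were examined, 36 gene lists of cell types, endothelial functions and technical signs were fixed from general knowledge of brain cell types. Of 461 members listed by name, 386 matched by symbol and 6 by Entrez identifier (Eltd1, Gpr124, Ptrf, Sdpr, Prkcdbp and Beta-s are the table's older symbols of Adgrl4, Adgra2, Cavin1, Cavin2, Cavin3 and Hbb-bs); 69 were not analysed here, and 153 further members came from symbol patterns. Lists with at least 4 tested members (34) were compared with all other genes by camera (limma 3.58.1), with an inter-gene correlation preset at 0.01. Benjamini-Hochberg adjustment was over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests a list's genes against no change, not against the other genes. Counts of members use the adjustment over all genes, and counts adjusted over the list alone are given beside them. Enrichment of the Gene Ontology terms that the table gives per gene was tested after the data were seen, with a one-sided Fisher's exact test against the 10885 tested genes that carry a term, over 1114 terms with 15 to 300 members and both directions.

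Genes named in the text were chosen by a rule fixed before the data were examined. It takes the genes of the gate, the driver and the reporter (Pecam1, Itgam, Tek, Rpl10a, Rangap1), and up to 3 members of each list with the highest mean level together with members called against the list's main direction. It also takes the 8 largest rises and 8 largest falls among called genes with the same direction in all 3 replicate numbers and a mean level in the upper part of the tested genes (above the median), without predicted or pseudogene names. Some genes that the rule selects are not reported here. Other list members named as examples were chosen after their values were seen.

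Whether the replicate numbers pair the libraries was checked from deviations from the fraction means: Input and Positive of one number correlated across genes at 0.45 (1222), 0.23 (1223) and 0.30 (1227), each above the highest correlation with another number (-0.05, 0.02 and 0.02). The numbers were therefore taken to pair the libraries. The main fit leaves this pairing out, and a fit with the replicate number as a block was run as an alternative. No label says whether a number marks an animal, so p-values measure the spread between these libraries.

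The edgeR step was tested on simulated data for Positive against Input, with counts of the 10989 real genes and 50 genes changed at each fold. It recovered 2% of genes changed 1.5-fold, 66% at 2-fold, 100% at 4-fold and 100% at 8-fold. Of 10772 unchanged genes 7 were called, 4.55% of the calls. Nearly all simulated genes were unchanged and shared 1 spread between libraries, while 6097 genes were called in the data. With so few changed genes the adjusted threshold is stricter, so these shares do not give the recovery in the data. In the same simulation camera called the 1 list that was raised and 0 of the others; that simulation drew genes independently, so it does not test lists whose genes move together. The alternatives were leaving out each library or both libraries of a number, the replicate block, DESeq2 (1.42.0) size factors, no scaling, other count minimums, DESeq2 and limma-voom as tools, prior counts of 0.5 and 5, a fold threshold and, added after seeing the data, limma on the deposited log2 values. Genes with near-identical copies, such as the haemoglobin, H2 and ribosomal protein genes, are uncertain where counting could split reads between copies, and overlapping or antisense genes are uncertain because the use of strand is not given.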

Results

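The series compared RNA of endothelial cells sorted from mouse brain (Positive) with RNA of the cell suspension they were sorted from (Input), in 3 libraries of each fraction. Input also holds endothelial cells, so a fold change here is the level in the sorted cells relative to the mixed suspension. The summed estimated counts were 31607627, 4814966 and 52283556 in Input replicates 1222, 1223 and 1227, and 23525401, 4772866 and 19708830 in the Positive libraries of the same numbers, a 10.95-fold range. The lower depth of both 1223 libraries gives their low genes more counting error. On the first principal component, which held 86.5% of the variance of log2 counts scaled to library size (CPM), the Input libraries lay between -82.3 and -78.4 and the Positive libraries between 79.2 and 81.5.

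The comparison of Positive with Input asked which transcripts the sorted endothelial fraction held more or less of than the brain suspension. All tested pan-endothelial (25), blood-brain barrier transporter (22), vascular basement membrane (13) and interferon response genes (17) rose. All tested genes of oligodendrocytes (14), astrocytes (17), ependymal cells (6), choroid plexus (8) and microglia (18) and 11 of 12 neuronal genes fell. Camera called these 10 lists at the preset correlation and none of them with an estimated correlation (adjusted p from 0.11 to 0.31). Of 10989 genes tested, 2870 (26.1%) were higher and 3227 (29.4%) lower in Positive (edgeR's quasi-likelihood test, adjusted p below 0.05), and 4892 did not pass. More than 8-fold differences were less frequent among higher genes (39) than among lower genes (867), and more than 2-fold differences numbered 1390 and 2414. Endothelial RNA in Input bounds the rise of endothelial genes. Of the genes kept, 1897 passed the deposited minimum in Input only and 583 in Positive only. The counts of higher and lower genes therefore do not compare the strength of the rises and falls. The minimum also favours a fall in genes kept through Input alone and a rise in genes kept through Positive alone. The shares of list members that fell or rose, and the list tests, carry the same limit. The direction was the same in all 3 replicate numbers for 2862 of the higher and 3220 of the lower genes. Without both libraries of replicate 1227, 1741 genes were higher.

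**Figure D1:**
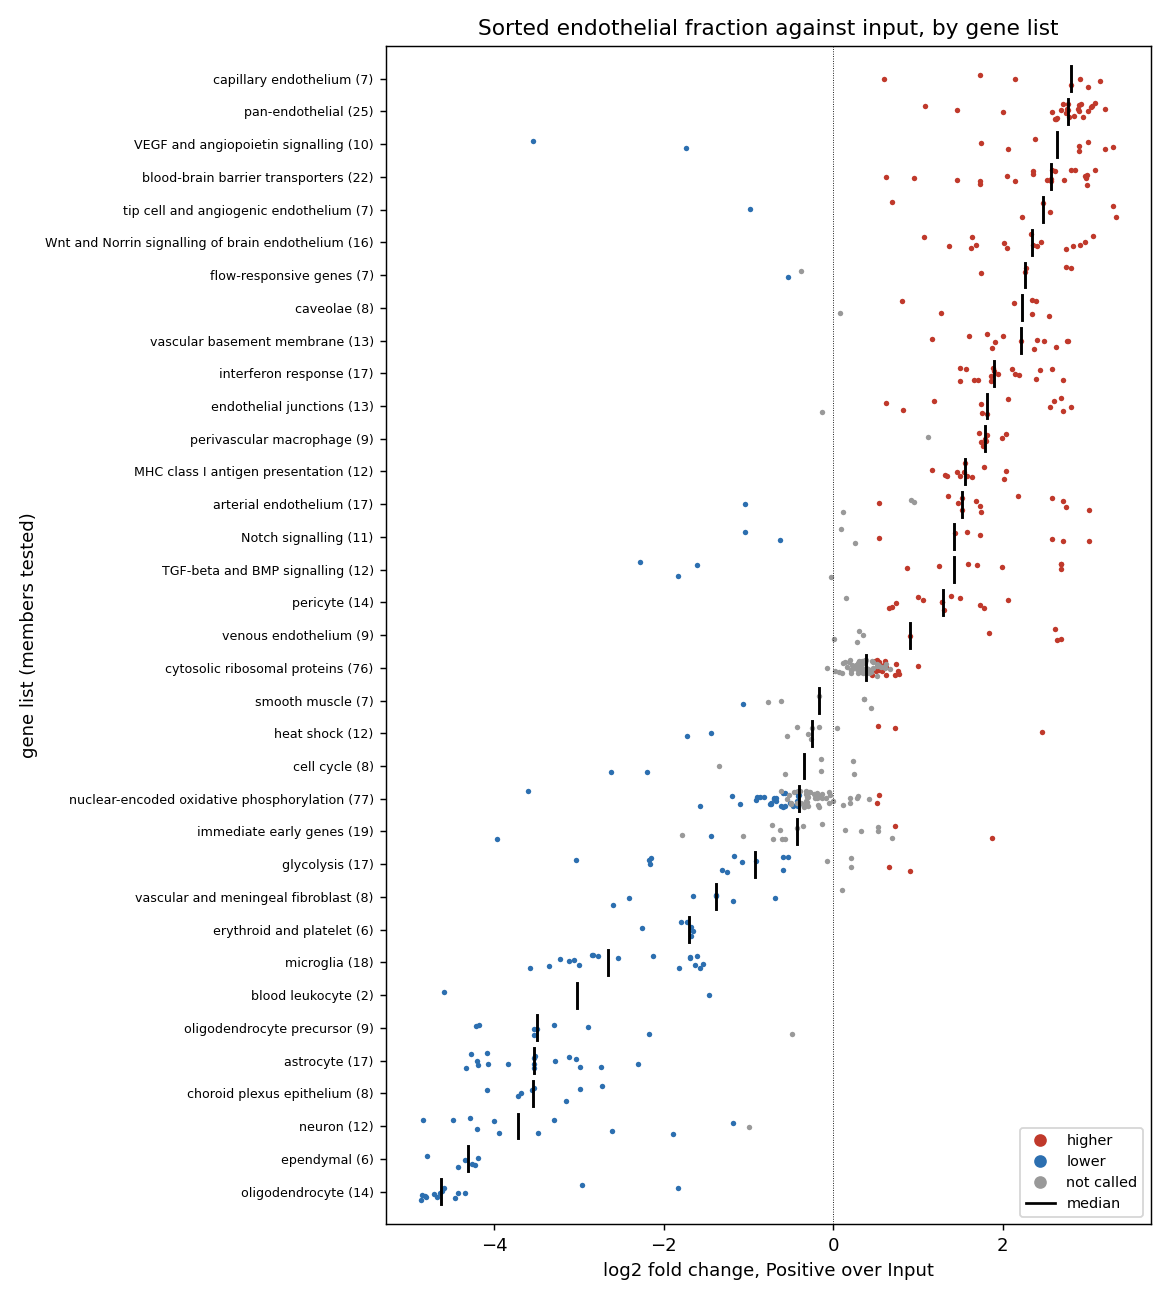
Log2 fold change of Positive over Input (horizontal axis) for each tested member of 35 gene lists (vertical axis, number of members in brackets, ordered by median); points are genes coloured by call and black bars are medians. Medians run from -4.63 for oligodendrocyte genes to 2.81 for capillary endothelial genes.

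The genes of the sorting gate check the sort and are not findings. Pecam1, which encodes CD31 (chromosome 11, 106654218 to 106715281, mm10), rose from 282 ± 16.8 to 2037 ± 55.2 CPM (SD, n = 3), a log2 fold change of 2.85 ± 0.13 (SE). Itgam, which encodes CD11b (chromosome 7, 128062640 to 128118491), fell from 445.9 ± 151 to 65.2 ± 19.7 CPM, a log2 fold change of -2.77 ± 0.31. Tek, the gene of Tie2 whose promoter drives Cre (chromosome 4, 94739300 to 94874939), rose from 201.6 ± 42.9 to 1362 ± 45.8 CPM. Rpl10a and Rangap1, mouse genes whose coding sequences are part of the NuTRAP reporter, rose by log2 1.70 ± 0.15 and 2.27 ± 0.13; from these counts, reads of the reporter cannot be separated from those of the mouse genes. All 5 passed the test, with adjusted p values of 2.7e-06 (Pecam1), 9.81e-05 (Itgam), 5.47e-06 (Tek), 2.07e-05 (Rpl10a) and 3.83e-06 (Rangap1).

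All 25 tested pan-endothelial genes rose, with a median log2 fold change of 2.77. Flt1, a VEGF receptor, went from 460.0 ± 37.5 to 3685 ± 385 CPM (log2 3.00 ± 0.16), and Podxl and Eng rose by log2 2.75 ± 0.17 and 2.69 ± 0.13. All 22 blood-brain barrier transporters rose (median 2.57): the glucose transporter Slc2a1 (chromosome 4, 119108745 to 119137329) from 937 ± 189 to 4798 ± 327 CPM, the organic anion transporter Slco1a4 by log2 2.97 ± 0.17 and the efflux pump Abcb1a by log2 2.86 ± 0.14. Among junction genes 12 of 13 rose (median 1.81), including Cldn5, the main claudin of brain endothelial tight junctions (762.4 ± 263 to 4916 ± 915 CPM), Ctnnb1 and Tjp1; Cldn12 did not pass (log2 -0.14, adjusted p = 0.51). All 16 Wnt and Norrin signalling genes rose (median 2.35), with Apcdd1 at log2 2.75 ± 0.18, Tnfrsf19 at 1.64 ± 0.17 and the transcription factor Foxf2 at 3.07 ± 0.14. All 13 vascular basement membrane genes rose (median 2.21), with Sparc at log2 1.17 ± 0.21, Fn1 at 2.40 ± 0.17 and Col4a1 at 2.76 ± 0.19. Of 8 caveolar genes 7 rose (median 2.23), among them Ptrf, Cav1 and Cav2, while Pacsin2 did not pass (log2 0.08, adjusted p = 0.73). Counts adjusted over the list alone were equal for these 6 lists. Camera called the lists higher (adjusted p from 2.3e-13 for pan-endothelial genes to 0.00023 for caveolae). None passed with an estimated correlation (adjusted p = 0.12, 0.11, 0.11, 0.11, 0.19 and 0.12, in the order given).

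Capillary endothelial genes rose in 7 of 7 cases (median log2 2.81), led by level by Spock2 (1248 ± 250 to 9383 ± 1270 CPM), Itm2a (log2 2.81 ± 0.23) and the chemokine Cxcl12 (log2 3.15 ± 0.14). Of 17 arterial genes 13 rose (median 1.52; 14 adjusted over the list alone), including the Notch ligand Jag2 (log2 2.58 ± 0.13) and Sema3g (2.18 ± 0.17); Unc5b did not pass (log2 0.12 ± 0.17, adjusted p = 0.573), and Hey2, a Notch target, fell (log2 -1.04 ± 0.26, adjusted p = 0.00815). Of 9 venous genes 5 rose (median 0.90), with Vwf at log2 2.61 ± 0.25 and Ephb4 at 2.69 ± 0.12. Of 7 tip cell genes 6 rose (median 2.48), with Pdgfb at log2 2.22 ± 0.13, Aplnr at 3.33 ± 0.40 and Apln at 0.69 ± 0.19, while the chemokine receptor Cxcr4 fell (-0.99 ± 0.20). Counts adjusted over the list alone were otherwise equal. Without both libraries of 1222 Hey2 lost its call (log2 -0.90), and without both of 1223 Apln did (log2 0.40). Camera called the 4 lists higher, and with an estimated correlation their adjusted p values were 0.11 (capillary), 0.13 (arterial), 0.13 (venous) and 0.15 (tip cell).

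In VEGF and angiopoietin signalling 8 of 10 genes rose (median log2 2.64), among them the receptors Flt1, Kdr (181.6 ± 26.3 to 1670 ± 69.6 CPM) and Tie1 (log2 2.90 ± 0.15). The 2 that fell encode ligands, Vegfa (log2 -3.55 ± 0.24) and Vegfb (-1.74 ± 0.25), while the ligand genes Angpt2 (3.30 ± 0.18) and Vegfc rose. In Notch signalling 7 of 11 rose (median 1.43), including Notch1 (log2 1.43 ± 0.18) and Notch4 (2.71 ± 0.12), and Hey2 and the feedback gene Nrarp (-0.63 ± 0.19) fell. In TGF-beta and BMP signalling 8 of 12 rose (median 1.42), including the endothelial receptors Eng and Acvrl1 (log2 2.68 ± 0.15) and Tgfbr2 (1.59 ± 0.16), and 3 fell: the receptor Tgfbr1 (-2.28 ± 0.27), the BMP target Id2 (-1.83 ± 0.16) and the ligand Bmp6 (-1.61 ± 0.22). Of 7 flow-responsive genes 5 rose (median 2.26), with Klf2 at log2 1.74 ± 0.38, Thbd at 2.26 ± 0.15 and Nos3 at 2.75 ± 0.14, and Asb1 fell (-0.53 ± 0.16). Counts adjusted over the list alone were equal for these 4 lists. Nrarp did not pass without Input 1227 (log2 -0.49) or Positive 1222 (-0.50), and Asb1 did not pass without Input 1222 (-0.48), Input 1227 (-0.56) or Positive 1222 (-0.53). Camera called the 4 lists higher, with adjusted p = 0.12, 0.18, 0.18 and 0.27 with an estimated correlation in the order given. With the replicate number as a block the TGF-beta and BMP list was not called (adjusted p = 0.053).

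All 12 genes of MHC class I antigen presentation rose (median log2 1.55), with H2-D1 from 468.6 ± 39.3 to 1453 ± 69.6 CPM, B2m at log2 1.17 ± 0.15 and H2-K1 at 1.545 ± 0.14; reads shared between H2 genes could be split by the counting. All 17 interferon response genes rose (median 1.90), with Ly6e at log2 1.945 ± 0.13 and the antiviral gene Ifitm3 at 2.145 ± 0.145. Counts adjusted over the list alone were equal. Camera called both lists higher (adjusted p = 7.18e-06 and 8.23e-08), and with an estimated correlation the adjusted p values were 0.12 and 0.18.

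Pericyte genes rose in 13 of 14 cases (median log2 1.29), with Vtn from 331.6 ± 52 to 692.8 ± 190 CPM, Rgs5 at log2 1.29 ± 0.19 and the receptor Pdgfrb at 0.74 ± 0.21; Anpep did not pass (0.15, adjusted p = 0.64). Without both libraries of 1227, 7 of the 14 passed, and Pdgfrb did not pass without Input 1222 (log2 0.66) or Positive 1227 (0.525). Of 7 smooth muscle genes, Tagln fell (log2 -1.07, adjusted p = 0.029; 0 fell when adjusted over the list alone) and the others did not pass: Myl9 had log2 0.36 ± 0.25, Myh11 -0.62 ± 0.30 and Mylk 0.45 ± 0.17. Leaving out single libraries moved the smooth muscle counts: 2 rose without Input 1223 (Mylk at log2 0.615), 3 fell without Input 1222 (Myh11 at -0.87), and the fall of Tagln ended without Input 1223, Input 1227, Positive 1222 or Positive 1223, where 0 fell. Fibroblast genes fell in 7 of 8 cases (median -1.38), with Igf2 at log2 -1.38 ± 0.15, Col1a2 at -1.38 ± 0.25 and Col1a1 at -2.41 ± 0.39; without both libraries of 1222, 4 fell. Camera called pericyte genes higher and fibroblast genes lower but not smooth muscle genes (adjusted p = 0.00030, 0.012 and 0.90). With an estimated correlation the adjusted p values were 0.33, 0.22 and 0.98.

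All 18 microglial genes fell (median log2 -2.66), with Csf1r at log2 -1.82 ± 0.40 and Cx3cr1 from 1469 ± 503 to 204.8 ± 65.2 CPM. Of 9 perivascular macrophage genes 8 rose (median 1.79), with Mrc1, the mannose receptor (chromosome 2, 14229414 to 14332023), at log2 2.04 ± 0.60, F13a1 at 1.73 ± 0.57 and Cd163 at 1.74 ± 0.58. These rises were uneven: Mrc1 stood at 1162, 417.7 and 160.3 CPM in Positive 1222, 1223 and 1227 against 145.2, 161.8 and 117.4 CPM in Input, and the list's median log2 difference within a number was 2.78, 1.12 and 0.13. The count of 8 fell to 2 without Input 1222, 2 without Input 1223, 0 without Input 1227 and 1 without Positive 1222, and to 3 with the replicate block, where F13a1 (log2 1.30) and Cd163 (1.325) did not pass. F13a1 and Cd163 did not pass without Positive 1222 (log2 0.695 and 0.74), Input 1222 (1.73 and 1.71), Input 1223 (1.78 and 1.85) or Input 1227 (1.67 and 1.65), and Mrc1 did not pass without Input 1227 (1.92), both libraries of 1222 (1.02) or both of 1223 (2.33). Of 18 genes in the blood leukocyte list 2 were tested, too few for a list test, and both fell: Ptprc at log2 -1.47 ± 0.49 and S100a9 at -4.60 ± 0.82. S100a9 was uneven in Input, at 83.8, 14.6 and 15.8 CPM in 1222, 1223 and 1227. Ptprc did not pass without Input 1222 (-1.20), Input 1227 (-1.48), Positive 1223 (-1.28) or Positive 1227 (-1.10). These 2 genes do not describe blood leukocytes as a whole. All 6 erythroid and platelet genes fell (median -1.70), with the haemoglobin genes Hba-a1, Beta-s and Hba-a2 at log2 -1.66 ± 0.36, -1.68 ± 0.35 and -1.80 ± 0.27. Counts adjusted over the list alone were equal for these lists. Camera called microglial and erythroid genes lower (adjusted p = 4.1e-06 and 0.0070) and perivascular macrophage genes higher at the edge of the threshold (0.0499); with an estimated correlation the adjusted p values were 0.31, 0.28 and 0.60, and fry did not call the macrophage list (0.17). The macrophage list was not called without Input 1222 (adjusted p = 0.077), Input 1223 (0.070), Input 1227 (0.070), Positive 1222 (0.071) or Positive 1223 (0.057).

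**Figure D2:**
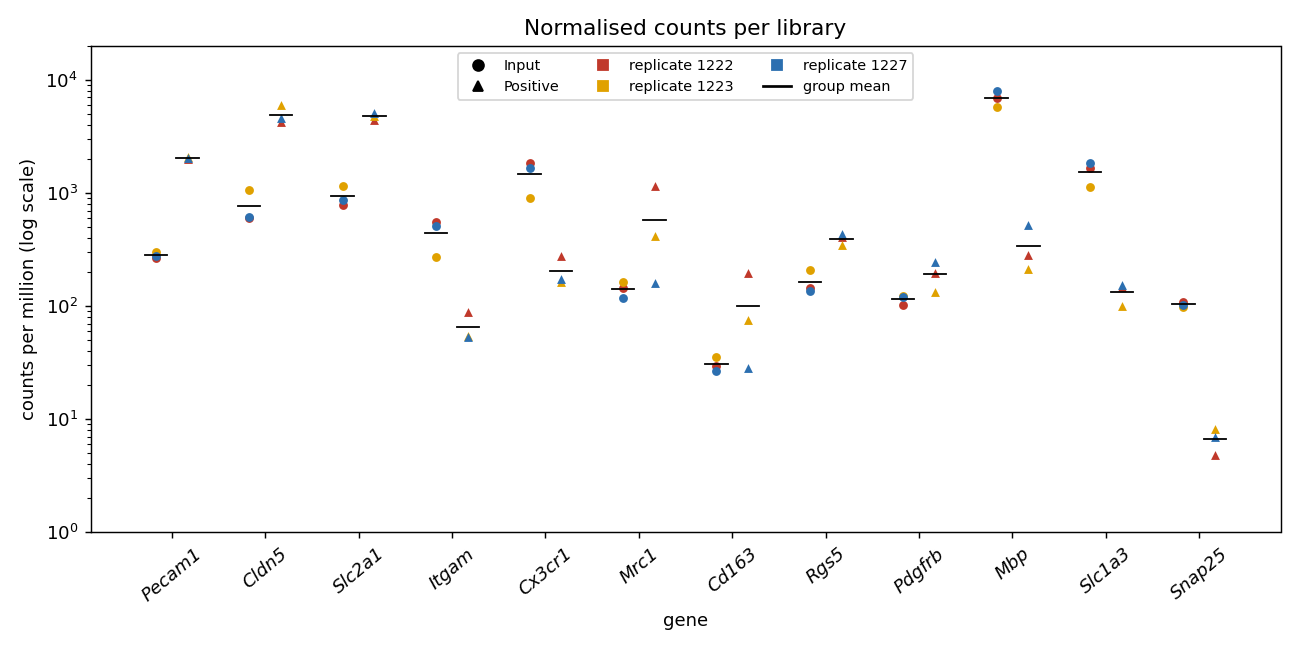
TMM-scaled CPM (vertical log axis) of 12 genes (horizontal axis) in each of the 6 libraries; circles are Input, triangles are Positive, colours are replicate numbers and bars are group means. Pecam1 lies at 2037 ± 55.2 CPM in the Positive libraries, while Mrc1 ranges from 160.3 to 1162 CPM there.

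Genes of neural cell types fell together. All 14 oligodendrocyte genes fell (median log2 -4.63), with the myelin genes Mbp from 6906 ± 1080 to 338.7 ± 162 CPM and Cnp at log2 -4.46 ± 0.35. Of 9 oligodendrocyte precursor genes 8 fell (median -3.50), with Gpr17 at log2 -4.22 ± 0.42, Enpp6 at -3.50 ± 0.35 and Pdgfra at -2.18 ± 0.62; Pdgfra did not pass without Input 1223 (-1.46) or both libraries of 1222 (-2.20), and Bmp4 did not pass (log2 -0.49, adjusted p = 0.21). All 17 astrocyte genes fell (median -3.53), with the glutamate transporters Slc1a2 and Slc1a3 at log2 -2.74 ± 0.32 and -3.52 ± 0.25. Of 12 neuronal genes 11 fell (12 adjusted over the list alone; median -3.72), with Tubb3 at log2 -4.20 ± 0.27, Camk2a at -4.48 ± 0.64 and Snap25 at -4.00 ± 0.21, and Nrgn did not pass (-1, adjusted p = 0.055). All 6 ependymal genes (median -4.31), among them Foxj1, Ccdc153 and Ak7, and all 8 choroid plexus genes (median -3.55), among them Ttr (log2 -2.73 ± 0.47), Kl and Clic6, fell. The other counts adjusted over the list alone were equal. Foxj1, Ccdc153 and Ak7, at means of 3.83, 1.14 and 2.40 CPM in Positive, were kept through Input alone, which favoured a fall. Camera called the 6 lists lower, and with an estimated correlation the adjusted p values were 0.26, 0.33, 0.20, 0.13, 0.16 and 0.28 in the order given.

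Of 17 glycolysis genes 12 fell (median log2 -0.92), with Aldoa at log2 -0.53 ± 0.15 and Gapdh at -1.17 ± 0.15, while Pkm did not pass (-0.07 ± 0.13, adjusted p = 0.65) and Ldha (0.90 ± 0.14) and Pfkl (0.65 ± 0.13) rose. Aldoa did not pass without Input 1227 (log2 -0.46), Positive 1222 (-0.48) or Positive 1223 (-0.47). Of 77 nuclear-encoded genes of oxidative phosphorylation 30 fell and 2 rose (27 and 2 adjusted over the list alone; median -0.40). Atp5b had log2 -0.43 ± 0.14, Atp5a1 -0.33 ± 0.13 and Sdha -0.195 ± 0.13, of which only Atp5b passed; the 2 that rose were Atp5j (0.51 ± 0.15) and Ndufa7 (0.55 ± 0.16). The count of 30 became 16 without Input 1227, 17 without Positive 1222, 18 without both libraries of 1223, 10 without both of 1227, 46 without scaling beyond library size and 15 by limma on the deposited log2 values. Neither rise passed without Input 1222 (Atp5j 0.44, Ndufa7 0.49), Positive 1223 (0.49, 0.46) or Positive 1227 (0.41, 0.49), or without scaling (0.36, 0.39), Atp5j did not pass without Input 1227 (0.52), and Atp5b did not pass without Input 1223 (-0.35), Input 1227 (-0.45), Positive 1222 (-0.39) or Positive 1223 (-0.40). Of 76 cytosolic ribosomal protein genes other than Rpl10a, 18 rose (median 0.39; 25 at an unadjusted p below 0.05 and 0 adjusted over the list alone, by edgeR), and the most abundant ones, Rpl4, Rpl13a and Rps3, had log2 0.38 ± 0.15, 0.34 ± 0.20 and 0.33 ± 0.21 without passing. With the replicate block 60 of them rose, Rpl4 (log2 0.38), Rpl13a (0.33) and Rps3 (0.33) among them. The 18 became 4 without Input 1222, 9 without Input 1227, 40 without Positive 1222 (Rpl4 among them, log2 0.48), 4 without Positive 1223, 4 without Positive 1227 and 4 without scaling. It became 5 without both libraries of 1223 and 1 without both of 1227. Camera called glycolysis and oxidative phosphorylation lower and ribosomal proteins higher (adjusted p = 0.018, 0.00086 and 0.00031), and with an estimated correlation the adjusted p values were 0.44, 0.61 and 0.64. Fry called glycolysis (adjusted p = 0.0018) but not oxidative phosphorylation (0.052) or ribosomal proteins (0.20).

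Among 19 immediate early genes, which dissociation can induce, 2 rose (Fosl2 and Ier2; 1 adjusted over the list alone) and 2 fell (Socs3 and Arc), and Fos, Jun and Zfp36 had log2 -0.72 ± 0.55, -0.57 ± 0.40 and -0.63 ± 0.48 without passing. With the replicate block 6 fell, Jun among them (log2 -0.66). Without Positive 1222, 10 fell, among them Fos (log2 -1.69), Jun (-1.16) and Zfp36 (-1.46), and the list was called lower (adjusted p = 0.045); without Input 1227, 6 fell, and in either case 1 rose instead of 2. Among 12 heat shock genes Hspb1, Bag3 and Hsp90ab1 (log2 0.53 ± 0.13) rose, Hsp90aa1 (-1.73 ± 0.16) and Hsph1 (-1.44 ± 0.24) fell, and Hspa8 did not pass (-0.25 ± 0.21); with the replicate block 4 fell. Of 8 cell cycle genes Mki67 and Top2a fell (log2 -2.20 and -2.63), and Pcna, Mcm2 and Mcm5 did not pass (-0.14 ± 0.13, 0.23 ± 0.22 and -0.57 ± 0.25). Camera called none of these 3 lists (adjusted p = 0.48, 0.95 and 0.19; with an estimated correlation 0.90, 0.98 and 0.53), while fry called cell cycle genes lower (adjusted p = 0.034). Hsp90ab1 did not pass without both libraries of 1222 (log2 0.49) or both of 1227 (0.55), and 1 cell cycle gene fell without both of 1222.

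Across the 34 lists tested, camera called 19 higher and 11 lower, and none with an estimated correlation, where 11 lists had an unadjusted p below 0.05 and the lowest adjusted p was 0.11. Fry called 17 higher and 11 lower: against camera it left out perivascular macrophage, ribosomal protein and oxidative phosphorylation genes and added cell cycle genes. Some lists share members, so their calls are not separate findings. Members also in another list were 6 of 11 for Notch and 5 of 10 for VEGF and angiopoietin signalling. For arterial and pan-endothelial genes they were 7 of 17 and 5 of 25.

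Among abundant genes chosen by the rule on size, the largest rises were those of Nos2 (log2 3.47 ± 0.27; chromosome 11, 78920859 to 78960124), the endothelial protocadherin Pcdh12 (3.38 ± 0.25), the apelin receptor Aplnr (3.33 ± 0.40), Angpt2 (3.30 ± 0.18), Hmcn1 (3.23 ± 0.37), Kdr (3.20 ± 0.16), Meox1 (3.16 ± 0.36) and Cxcl12 (3.15 ± 0.14). Nos2, the inducible nitric oxide synthase, stood at 7.21 ± 2.80 CPM in Input and 85.0 ± 9.52 CPM in Positive, well below Kdr in both. The largest falls included those of Lgi3 (log2 -4.89 ± 0.44; chromosome 14, 70530821 to 70538324), Calb2 (-4.88 ± 0.33), Tmeff2 (-4.87 ± 0.30), Mog (-4.87 ± 0.41), the lineage factor Olig2 (-4.85 ± 0.40), Mag (-4.85 ± 0.50) and Gjb1 (-4.82 ± 0.51). Mog, Mag and Gjb1 are also in the oligodendrocyte list. The rule itself required a call and the same direction in the 3 replicate numbers, so neither is a result. Adjusted p values ran from 2.7e-06 (Cxcl12) to 0.000138 (Aplnr).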

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

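The counts of higher and lower genes and of lists stayed within 1.5 times their values in most settings. The exceptions follow. Without both libraries of replicate 1227, 1741 genes were higher instead of 2870. With as many libraries in the fit, 2312 were higher without both of 1222 and 2571 without both of 1223. The number of libraries alone therefore does not account for 1741, and the cause was not tested. Over all settings that left out libraries, the higher genes ran from 1741 to 2755, the lower genes from 2393 to 3207, the higher lists from 18 to 19 and the lower lists from 11 to 12. A threshold of 2-fold left 1390 higher genes by its construction. With an estimated correlation camera called 0 lists higher and 0 lower. For the junction, capillary, venous, and TGF-beta and BMP lists, the values argue against correlation between genes as the cause. Their estimated correlations were -0.02, -0.01, -0.04 and -0.03, below the preset 0.01, yet adjusted p rose to 0.11, 0.11, 0.13 and 0.18. What else differs between the preset and estimated forms of camera was not tested. With the replicate block 3298 genes were higher and 3482 lower, with 18 lists higher and 11 lower; the changed calls under the block are given with the results, Atp5a1 also passed (log2 -0.33), and it changed no other call of a named gene or list. Without scaling beyond library size 2165 genes were higher and 3666 lower, and the median log2 of all genes was -0.128 instead of 0.029, so values there are relative to a shift of that size. Of 1995 values of 133 named genes under alternatives, 1896 kept direction and side of the threshold, 74 no longer passed, 21 newly passed and in 4 the sign changed or the value fell to 0. These 4 belong to genes that did not pass: Unc5b without Input 1222 (-0.015), without both 1222 libraries (-0.064) and without scaling (-0.035), and Hspa8 without Input 1223 (0). Over the settings that left out libraries Unc5b ran from -0.064 to 0.298 and Hspa8 from -0.475 to 0; the cause was not tested. Prior counts of 0.5 and 5 do not enter the test of genes, and the setting with no filter removed nothing, so for genes these say nothing of stability; in the list test a prior count of 0.5 left 18 lists higher, without perivascular macrophage genes (adjusted p = 0.051). The alternatives planned for normalised values did not apply, since counts were used, and limma on the deposited log2 values was chosen after seeing the data (3253 higher, 2950 lower). Changes of 1.5-fold were recovered in 2% of simulated cases, where few genes changed and the adjusted threshold was stricter than in the data. In the data 2870 genes were higher and 1390 of them more than 2-fold, so smaller changes also passed. Whether the share of changed genes, depth, replicate number or spread limits the simulated recovery was not tested.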

Other observations

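Of the tests in this part, the splits of the libraries, the tests of depth, of microglial genes, of vessel wall cells and of ribosomal protein genes, that of reporter reads, and the Gene Ontology enrichment were chosen after the results they bear on were seen; the further macrophage and pericyte genes were listed, and their bounds written, before those values were seen.

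Gene Ontology terms were tested beside the fixed lists, whose members they share in part, and the genes named in this paragraph were chosen after their values were seen. Of 1114 terms, 63 were enriched among higher and 111 among lower genes (one-sided Fisher's exact test, adjusted p below 0.05). Angiogenesis held 73 higher genes of 140 against 36.7 by chance (adjusted p = 1.2e-08), with the hypoxia-inducible factor Epas1 at log2 2.34 ± 0.14, and vasculogenesis held 32 of 44. Focal adhesion held 39 of 76 against 19.9 (adjusted p = 0.00014), with the integrin Itgb1 (1.46 ± 0.12) and Tns1 (2.10 ± 0.15), and stress fibres 26 of 46 against 12.1, with the non-muscle myosin Myh9 (2.09 ± 0.18) and Actn4 (1.81 ± 0.13).

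Among lower genes, synapse held 143 of 242 against 71.3 by chance (adjusted p = 8.4e-19), with the astrocyte genes Slc1a2 and Slc1a3 among them. Potassium ion transmembrane transport held 27 of 31 (adjusted p = 1.2e-08), led by Kcnj10 (log2 -3.55 ± 0.235). Lysosome held 101 of 196 against 57.8 (adjusted p = 1.3e-08), with Psap (-1.06 ± 0.13), Cst3 (-1.51 ± 0.13) and Ctsd (-1.60 ± 0.19). Cholesterol biosynthesis held 16 of 23 against 6.8 (adjusted p = 0.0023), with Hmgcs1 at log2 -2.12 ± 0.15 and Insig1 at -1.01 ± 0.17. Genes that share a term are not independent, so these p values are too small where they move together.

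Perivascular macrophage genes differed between Positive libraries, with list medians of log2 CPM of 6.68, 5.11 and 4.01 in 1222, 1223 and 1227, although the gate was CD11b-negative; Rn45s (11660, 4851 and 2795 CPM), Fos (1052, 319.1 and 231.5) and Zfp36 (894.5, 301.5 and 246.3) fell in the same order, so Positive 1222 stands apart in more than these genes. Sequencing depth is argued against, because totals were near in Positive 1222 and 1227 (23525401 and 19708830) and Positive 1223, with 4772866, had all 9 genes above 1227 (median log2 1.26). Microglial RNA is argued against too, because 7 microglia-restricted genes had a median log2 of 0.23 for Positive 1222 over Positive 1227, though the full microglial list, some of whose genes macrophages share, had 1.03. Macrophage RNA in amounts that differ between the sorted libraries stays a candidate explanation: 20 further macrophage genes were all higher in Positive 1222 than in Positive 1227 (median log2 2.21), with Stab1 at 1399, 622.6 and 364.1 CPM and Lyz2 at 465.7, 186.9 and 107.8 CPM in 1222, 1223 and 1227; against Input their median log2 was 0.15, with 3 higher and 2 lower. Endothelial cells can express some of these genes, such as Stab1, Lyve1 and Cd36, and the design names no biological difference between these libraries, so none was tested. Whether macrophages carried the EGFP label that the gate also selects was not tested.

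Pericyte genes were higher in Positive although the gate selects CD31. The fibroblast list had a median log2 of -1.38 (interquartile range 0.79) and the smooth muscle list -0.17 (1.06). Neither list rose with the pericyte genes. Whether RNA of vessel wall cells of every kind was carried cannot be decided from this. The fibroblast list includes meningeal genes, and meningeal cells in Input would lower a fold change against it. Pericyte RNA carried with sorted endothelial cells may account for the rise of the pericyte list. Of 18 further pericyte genes 11 were higher and 3 lower (Zic1, Slc30a10 and Itga7), with a median log2 of 0.78. Their interquartile range of 1.63 exceeds that median, and Ebf1 (2.61) and Gjc1 (2.36) rose nearly as much as endothelial genes, so expression in endothelial cells themselves stays open and was not tested.

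Rpl10a rose more than every other ribosomal protein gene tested. It lay 0.69 log2 units above the highest of them (Rpl38, 1.01), which restates the pattern and does not decide whether a rise shared by ribosomal protein genes adds to it. Reads of the NuTRAP transgene counted to the mouse gene may add to the log2 fold change of 1.70, and to that of Rangap1 (2.27); this cannot be told apart from higher expression of the mouse genes, because the sequence of the reads was not analysed here.

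With 10 splits of the 6 libraries into groups of 3, a share under 0.05 cannot be reached, and each of the other 9 sets 2 libraries of a fraction and 1 of the other against the rest, so it keeps part of the difference between the fractions. The real split gave 2870 higher and 3227 lower genes, and 1 split, the real one, gave as many in 1 direction; the highest count of the other splits was 0 (edgeR, with 1 to 268 genes at an unadjusted p below 0.05). For lists the real split gave 19 higher and 11 lower, and the highest count in 1 direction elsewhere was 18, so 1 split gave at least 19 and 8 of the 10 at least 11. The other 3 splits that also part all 3 number pairs called 25, 23 and 26 lists and 0 genes.

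Plekhh2 held 1.414% of the counts of Input 1223 (13600 CPM) against 0.008% and 0.004% in the other Input libraries. In Positive 1222, 1223 and 1227 it held 0.02%, 0.195% and 0.177%. The ribosomal precursor RNA gene Rn45s held 1.096% of the counts in Positive 1222 and between 0.124% and 0.513% in the other 5 libraries. Prnd had the highest log2 fold change of all called genes (4.48 ± 0.29) at a level of 63.1 ± 21.8 CPM in Positive.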
